A study of Mus musculus with 2 samples.

How the data were processed

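Droplet libraries of sorted CD45-positive cells from liver tumours were analysed, 1 from mice fed Akkermansia muciniphila (AKK) and 1 from mice given PBS, as the samples' titles name them. Tumours were digested with collagenase, and leukocytes were enriched on Percoll, freed of red cells and sorted as live CD45-positive cells before 10x Genomics 3′ v3 library preparation and sequencing on a NovaSeq instrument, per the labels' protocols. Each deposited matrix holds raw counts of unique molecular identifiers (UMIs) per gene and barcode, with PCR duplicates already collapsed and no normalization. Cell Ranger 7.1.0 wrote the matrices, per the file headers, whereas the submitters' processing notes list Cell Ranger 5.0.1 and the mouse build mm10. Those releases differ in whether intronic reads are counted by default, and the intron setting and the annotation release are not given in the sources used here, so the UMI levels cannot be assigned to exons alone. The lowest UMI total per barcode was 500 in the PBS and 501 in the AKK matrix, so the deposited barcodes had been filtered. Of the 32285 gene identifiers, 32235 (99.8%) were found in GENCODE mouse release M21 on GRCm38, the assembly of mm10, which gave the coordinates.

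Of 11698 barcodes, those with at least 200 genes and under 15% of UMIs from mitochondrial genes were kept, which removed 255 PBS (5.01% of barcodes were over the mitochondrial limit) and 93 AKK barcodes (1.41%). Barcodes with fewer than 1000 UMIs were 5.48% of the PBS and 2.36% of the AKK barcodes. Doublets were scored per library with Scrublet, whose automatic threshold marked 0.0786% of PBS and 1.01% of AKK barcodes and was not used; the barcodes with the highest scores were removed instead, at a share fixed beforehand of 0.8% per 1000 barcodes, which took 195 PBS and 345 AKK cells. The kept 4638 PBS and 6172 AKK cells held 60224862 and 67697651 UMIs, with medians of 6747 and 6367.5 per cell. Both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method at resolution 1.0, which gave 37 clusters.

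Clusters were named from 21 marker sets fixed before the data were examined, by the mean log2 ratio of the markers (CPM + 10) to the median of the clusters with at least 30 cells, a minimum score of 1.0 and at least 3 markers detected in 20% of cells. A cluster of at least 60 cells in which a second class scored within 1.5 was clustered once more (1000 variable genes, 10 components, resolution 0.5). A cluster stayed unnamed where markers of another class outnumbered its own among its 10 leading genes, or where its median UMI count was low without a marker among those genes. It also did where at least 2 of 4 granule genes of myeloid precursors were among the first 10 genes ranked against the median of the clusters. A further rule, for clusters with no marker of their class among the first 50 genes of that second ranking, left none unnamed. The scoring settings were chosen after the clusters had been seen. They left 4 clusters unnamed: a shallow cluster that scored nearest to neutrophils among the marker sets (3.75% of PBS and 0.616% of AKK cells, median 684.5 UMIs), a cluster led by Camp and Ngp (0.992% and 0.308%) and 2 clusters of myeloid precursors (0.539% and 0.680%, and 0.647% and 0.340%). The 10 leading genes of the shallow cluster included Ccr3, Car4 and Alox15 but no neutrophil marker, whereas its second ranking began with the neutrophil marker Retnlg. No marker set was for eosinophils, so the type of the shallow cluster stays open. The other 33 clusters fell into 15 classes, each called X-like for its markers, and values of a class's own markers are named as such in the text. The alternative activation list held 6 markers of some class among the measured members in neutrophil-like, 7 in macrophage-like and 5 in monocyte-like cells, and the MDSC-associated list 3 in each.

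Shares of kept cells have exact (Clopper-Pearson) 95% binomial intervals and differences of shares Newcombe intervals. UMIs were summed per library and class, for classes with at least 100 cells in each library and for all kept cells, and scaled to CPM of the class total. A gene's ratio, AKK over PBS, has an exact conditional binomial 95% interval. UMIs of 1 library are not replicates, so these intervals cover counting error only and hold no spread between animals. For 23 gene lists fixed beforehand, the median log2 ratio of CPM + 5 was taken over members with at least 20 UMIs, where at least 5 were measured, with an interval from 1000 Poisson draws and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists fixed for cDC1-like, cDC2-like and gamma-delta T-like cells were not computed, since these classes had fewer than 100 cells in a library. Shares of cells with a UMI were taken after thinning each cell of a class to the 10th percentile of UMIs, beside the unthinned share and the share in a comparison class thinned to the same number. That class was neutrophil-like for lymphocytes and T-like for myeloid cells, and it gives no background for Mki67 and Cd274, which T-like cells are not known to lack. Medians over members above the free RNA limit could not be taken, for too few members, for alternative activation in neutrophil-like and monocyte-like cells, lipid-associated and cell cycle genes in neutrophil-like cells, MHC class II in both of those classes, cell cycle in NK/ILC1-like and B-like cells, type I interferon in B-like and tumour/epithelial-like cells, and NF-kB and hypoxia genes in B-like cells.

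Genes were named by a rule fixed before the data were examined: at least 50 CPM in 1 library, at least 50 UMIs over both, and, against free RNA, a CPM of at least 0.2 of that in the class with the highest level (of classes with at least 20 cells, a minimum set after the clusters had been seen), without mitochondrial, ribosomal, haemoglobin, Gm, Rik and receptor segment genes. Ranked by the log2 ratio of CPM + 5, the 10 highest and lowest were taken in monocyte-like, macrophage-like, neutrophil-like and T-like cells, the 5 highest and lowest in other classes and over all kept cells, together with the 2 highest and 2 lowest members of each list. Which of these 418 names the text prints was decided after their values were seen, with a preference for those that moved little between settings; Ptprc, Alb, Ddx3y, Il17a, Cd274 in monocyte-like and Ctla4 in T-like cells and, in tumour/epithelial-like cells, S100a8 and S100a9 lie outside the rule, and the choice to print them was made after their values were seen. Genes of the stefin, Klra, H2, Gbp, Ifit and immunoglobulin constant families have near-identical copies between which reads could be split, so their single values are uncertain. Some single genes are not reported here, in the text or the figure of list members, while the list medians include all measured members. The calculation was tested on simulated counts with 200 genes changed by known folds in each comparison. In the neutrophil-like comparison (12734 genes) 100% of genes changed 1.5-fold were recovered, and the intervals of 96.3% of unchanged genes held their simulated ratio. In the B-like comparison (9187 genes) these were 91.2% and 95.9%. The counts were Poisson draws around the class means, and the changed genes had a mean of at least 50 CPM. No spread between cells or animals was simulated, so the test covers counting error only. The alternatives were other limits on genes, mitochondrial share, UMIs and doublets, other clustering settings, each library clustered alone, class from each cell's own markers, the mean of CPM over cells, scaling by the median of gene ratios, another pseudocount or UMI minimum, equal weights for clusters or classes, and no thinning. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, scanpy 1.11.5 and matplotlib 3.10.9.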

Results

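Live CD45-positive cells, that is leukocytes, were sorted from liver tumours of C57BL/6 mice and profiled by droplet single-cell RNA-seq with the 10x Genomics 3′ v3 kit. The tumours grew from RIL-175, a mouse hepatocellular carcinoma line that carried luciferase and was implanted in the liver. The mice ate a methionine- and choline-deficient (MCD) diet, a model of liver cancer in fatty liver disease. They received by mouth either Akkermansia muciniphila (AKK), a gut bacterium that degrades mucin, at 5e9 colony-forming units, or phosphate-buffered saline (PBS). Feeding began 2 weeks ahead of the diet, the diet ran for 2 weeks before the cells were implanted, and feeding stopped for 6 days after surgery. The comparison asks how the bacterium bears on innate immunity and immune regulation in the tumour. There was 1 library per group and there were no replicates, so nothing was tested between the groups. Both values are given, "higher" and "lower" describe these libraries, and every interval is a 95% interval that covers counting error only. Whether a library pooled several mice is not given in the sources used here. The PBS library held 5088 barcodes and 64731604 UMIs (transcript counts), with a median of 6558.5 UMIs and 2023 genes per barcode. The AKK library held 6610 barcodes and 74495998 UMIs, with medians of 6488 and 2274. After filtering, 4638 PBS and 6172 AKK cells were kept.

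Lymphocytes made up a larger part and macrophages a smaller part of the leukocytes from the AKK tumours. T-like, gamma-delta T-like, NK/ILC1-like, B-like and plasma-like cells together were 32.8% of kept cells in the AKK library (31.7 to 34.0) and 21.04% in the PBS library (19.9 to 22.2). The difference was 11.8 percentage points (10.1 to 13.4). T-like cells were 14.8% against 9.98%, a difference of 4.84 points (3.60 to 6.07). NK/ILC1-like cells, the innate cytotoxic lymphocytes, were 8.15% against 5.84% (difference 1.34 to 3.26 points) and B-like cells 4.62% against 3.51% (0.348 to 1.84). The antibody-secreting plasma-like cells were 3.61% against 1.12% (1.93 to 3.05) and gamma-delta T-like cells 1.64% against 0.582% (0.664 to 1.45). Macrophage-like cells were 8.72% in the AKK and 13.3% in the PBS library, a difference of -4.54 points (-5.76 to -3.35). For every 100 T-like cells there were 58.8 macrophage-like cells in the AKK and 133 in the PBS library.

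Neutrophil-like cells were the largest class in both libraries, at 41.7% in the AKK and 44.9% in the PBS library (difference -5.08 to -1.31 points). Classical monocyte-like cells were 5.95% against 6.86% (-1.86 to 0.0176), a difference within counting error. Nonclassical monocyte-like cells numbered 58 against 9, and a cluster mostly of 1 library may be a property of that library. Among dendritic cells, the cDC2-like class was 2.61% against 1.79% (0.257 to 1.37). Its largest cluster was at 1.34% in both libraries. Smaller clusters made up the difference, with 51 against 18 and 27 against 3 cells. The latter lay mostly in 1 library and scored next nearest to pDC-like cells. The difference lay within counting error for cDC1-like cells (0.907% against 0.841%), plasmacytoid pDC-like cells (1.30% against 0.906%) and mature DC-like cells (0.421% against 0.259%). It also did for basophil/mast-like cells, at 0.843% against 0.625%. Most of that class lay in a mast cell cluster in the PBS library (28 of 29 cells) and in a basophil cluster in the AKK library (36 of 52). Tumour/epithelial-like cells, which the CD45 sort should remove, were 1.86% against 3.43%. Cells of unnamed clusters were 1.94% against 5.93%, in the PBS library mostly barcodes of the shallow cluster, whose cell type is open. Sorting, the Percoll step and the loss of fragile cells also set these shares, and each share stands relative to the other classes. With each library clustered alone, the neutrophil-like difference was -10.3 points and the monocyte-like one 0.216. In that setting no cDC1-like, mature DC-like or nonclassical monocyte-like class was named in the PBS library, and its cDC2-like share was 3.26%, so these classes cannot be compared there. The cDC1-like difference was 0.441 points with each cell's class from its own marker score, and the basophil/mast-like one -0.403 among barcodes with at least 1000 UMIs. The macrophage-like difference was -2.50 points at a clustering resolution of 2.0.

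**Figure D1:**
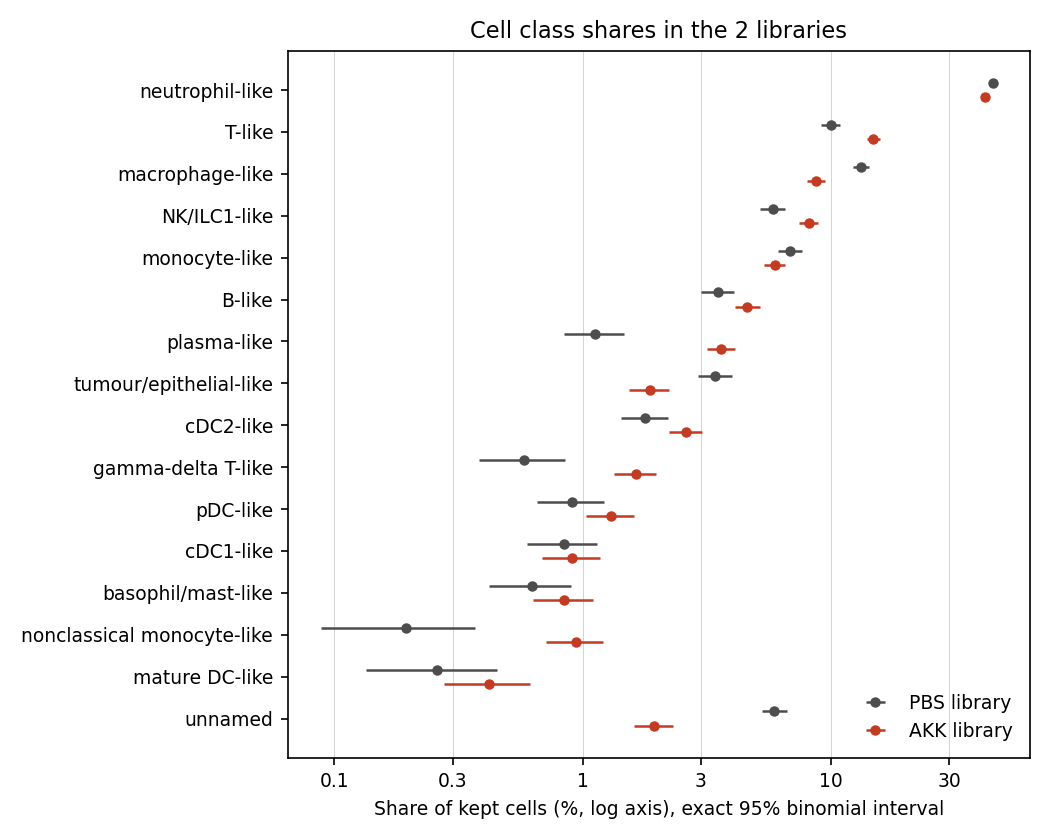
Share of kept cells (%, log axis) in each cell class, with PBS in grey and AKK in red and bars for exact 95% binomial intervals (counting error only). T-like cells lie at 14.8% in the AKK against 9.98% in the PBS library and macrophage-like cells at 8.72% against 13.3%.

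In neutrophil-like cells, genes induced by interferon-gamma were higher in the AKK library. All 17 measured members of the interferon-gamma response list were higher, with a median log2 ratio of 0.98 (0.86 to 1.17, percentile 100 among matched random lists). The guanylate-binding protein gene Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, GRCm38) stood at 382 CPM (UMIs scaled to the class total) against 84.6, a ratio of 4.51 (4.21 to 4.84). The ratio was 4.32 for Gbp5, and 3.40 and 2.66 for the immunity-related GTPase genes Irgm1 and Igtp. Cxcl9 and Cxcl10, chemokines that draw CXCR3-bearing T and NK cells, had ratios of 15.9 (10.2 to 26.0) and 2.29 (2.15 to 2.45). Cxcl9 was at only 1.77 CPM in the PBS library. Genes of antigen presentation by MHC class I were higher in 13 of 13 members (median 0.64), among them the transactivator gene Nlrc5 at 2.42 and the peptide transporter gene Tap1 at 2.02. The type I interferon list was higher in 16 of 16 members (median 0.53), with Ifit1 at 2.11. The MHC class II list was higher in 11 of 11 members (median 0.29), but 0 of these passed the limit against free RNA, so RNA of other cells is not excluded.

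Other neutrophil-like genes were lower in the AKK library. Cd38, an ectoenzyme that splits NAD, was at a ratio of 0.288 (0.249 to 0.332), the inhibitory Fc receptor gene Fcgr2b at 0.468 and the glucocorticoid-induced Fkbp5 at 0.423. The cysteine protease inhibitor gene Stfa2, uncertain because it has near-identical copies, was at 0.218 (0.191 to 0.249). The alternative activation list was lower in 11 of 14 members (median -0.25), with the chitinase-like gene Chil3 at 0.531 (0.514 to 0.547). Only 4 of these 14 members passed the limit against free RNA, so RNA of other cells is not excluded. The list linked to myeloid-derived suppressor cells (MDSC) was lower in 13 of 19 members (median -0.16), with Wfdc17 at 0.550. In the same list, the prostaglandin synthase gene Ptgs2 was at 1.29 and Cd274, which encodes PD-L1, at 1.26. The granule list had a median of -0.16 and the hypoxia and glycolysis list -0.13. The lists for tumour-associated neutrophils and classical activation had medians of 0.17 (percentile 99.1) and 0.13 (percentile 93.2, within the range of matched random lists). In the former the chemokine gene Ccl4 was at 1.74 (1.70 to 1.77). Medians were nearer to 0 for myeloid chemokines (-0.03), NF-kB and TLR genes (-0.02), cell cycle genes (-0.02), dissociation stress genes (-0.01), lipid-associated genes (-0.08) and pro-angiogenic genes (-0.10). Each cell was thinned to 2319 UMIs, which left out 291 AKK and 175 PBS cells. After that, 79.0% of AKK against 70.4% of PBS cells had a Ptgs2 UMI (unthinned 84.7% against 82.4%). In T-like cells the Ptgs2 shares were 6.44% and 8.47% in cells thinned to the same number. The interval of the difference in thinned shares included 0 for Cd274, the arginase gene Arg2 and Siglecf. With no doublets removed, the alternative activation median was -0.14, the tumour-associated neutrophil median 0.25 and the NF-kB median 0.06. The MDSC median was -0.07 over members above the free RNA limit, the granule median 0.07 with clusters weighted alike, and the Stfa2 log2 ratio -1.09 in place of -1.98 with each cell weighted alike.

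In classical monocyte-like cells, most genes of the interferon-gamma response list were higher and most of the NF-kB and TLR list lower in the AKK library. The median mitochondrial share of this class was 3.31% in the AKK and 4.72% in the PBS library, with medians of 13908 and 12882 UMIs. The interferon-gamma response list was higher in 13 of 15 measured members (median log2 ratio 0.74, 0.66 to 0.97). The GTPase genes Gbp2 and Ifi47 had ratios of 2.62 (2.22 to 3.09) and 3.39 and Cxcl9 a ratio of 20.3 (11.9 to 37.6), from 2.60 CPM. The members that were lower were Cxcl10 (0.560) and Gbp5 (0.556). MHC class II genes, which present antigen to CD4 T cells, were higher in 10 of 11 (median 0.67), with H2-Aa at 2.05 (1.88 to 2.24). Only 2 of these members passed the limit against free RNA, so RNA of other cells is not excluded here either. MHC class I genes were higher in 12 of 13 (median 0.46). Samhd1, a nucleotide hydrolase that restricts viruses, was at 1316 against 512 CPM, a ratio of 2.57 (2.46 to 2.68). The NF-kB and TLR list was lower in 14 of 17 members (median -0.71, -0.80 to -0.59, percentile 0). In it, the cytokine gene Il1a was at 0.233 (0.208 to 0.260), the neutrophil chemokine gene Cxcl2 at 0.346 (0.338 to 0.354) and Tnf at 0.375.

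Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), the gene of an anti-inflammatory cytokine, had a ratio of 0.158 (0.118 to 0.208) in monocyte-like cells. Cd38 was at 0.225 (0.196 to 0.257) and the microRNA-155 host gene Mir155hg at 0.235. The double-stranded RNA sensor gene Ifih1 was at 0.256 (0.231 to 0.282) and Oasl1 at 0.261, although the type I interferon list was higher in 11 of 16 members (median 0.40). Medians were below 0 for the MDSC-associated (-0.62), myeloid chemokine (-0.57), lipid-associated (-0.45), classical activation (-0.40) and pro-angiogenic lists (-0.39). They were also below 0 for alternative activation (-0.34), hypoxia and glycolysis (-0.26) and neutrophil granule genes (-0.51), the last with Lcn2 at 0.244. For alternative activation only 4 of 12 measured members passed the limit against free RNA, so RNA of other cells is not excluded. The cell cycle list had a median of 0.03 and the dissociation stress list 0.12. Beside the granule, MDSC-associated and NF-kB lists, the neutrophil markers allowed for 7.06% neutrophil RNA in the PBS and 2.68% in the AKK profile of this class. These shares take the marker RNA to come from neutrophils. Cells were thinned to 4235 UMIs, which left out 42 AKK and 27 PBS cells. For the lipid receptor gene Trem2, 10.8% of AKK against 18.6% of PBS cells had a Trem2 UMI (unthinned 29.97% against 40.3%), with 0.858% and 0.491% in T-like cells. For the arginase gene Arg1 the shares were 8% against 13.4% (unthinned 14.99% against 28.0%), with 1.961% and 4.42% in T-like cells thinned alike. For Spp1, the osteopontin gene, they were 29.5% against 39.9% (unthinned 60.5% against 71.1%), with 20.2% and 26.8% in T-like cells. For Cd274 they were 35.4% against 48.1% (unthinned 61.6% against 72.0%), with 41.8% and 40.8% in T-like cells, although its CPM ratio was 1.06 (0.976 to 1.16). For Mki67 they were 15.1% against 22.3% (unthinned 23.4% against 35.8%), with 10.3% and 9.09%. T-like cells are not known to lack Cd274 or Mki67, so these shares have no background here. The interval of the difference included 0 for Mrc1 and Nos2. With each cell weighted alike, the MDSC-associated median was -0.39, the hypoxia median -0.01 and the chemokine median -0.35, and with no doublets removed the lipid-associated median was -0.02. The Gbp5 log2 ratio of -0.77 was -0.13 with each cell's class from its own marker score, and the H2-Aa log2 ratio of 1.01 was 0.49 with at least 500 genes per cell.

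Macrophage-like cells had a median mitochondrial share of 2.23% in the AKK and 2.75% in the PBS library, with medians of 12418.5 and 16641 UMIs. In macrophage-like cells, MHC class II genes were higher in 11 of 11 members (median log2 ratio 0.50, 0.41 to 0.55). The class II transactivator gene Ciita was at a ratio of 1.87 (1.68 to 2.10) and H2-Ab1 at 2917 against 1911 CPM. MHC class I genes were higher in 13 of 13 (median 0.37) and interferon-gamma response genes in 14 of 17 (median 0.42, 0.31 to 0.54). Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) was at 3.25 (3.02 to 3.51), whereas Cxcl10 was lower, at 0.508 (0.482 to 0.536). The lectin gene Mgl2 was at 2.78 (2.57 to 3.02), the cytokine receptor gene Il21r at 2.88 and Ass1, which remakes arginine from citrulline, at 2.71. Samhd1 was at 2.03 and Pdcd1lg2, which encodes the PD-1 ligand PD-L2, at 2.05 (1.85 to 2.27). The adhesion molecule gene Vcam1 had a ratio of 0.145 (0.125 to 0.168), the fibroblast activation protein gene Fap 0.226 and Adamdec1, a protease of tissue macrophages, 0.227. The chemokine gene Ccl4 was at 939 against 3059.7 CPM, a ratio of 0.307 (0.299 to 0.315). Ifih1 was at 0.258 (0.245 to 0.272), Rsad2 at 0.290 and Oasl1 at 0.296. The type I interferon list had 10 members lower and 7 higher, with a median of -0.14 and a mean of -0.37. That median lay below the range of matched random lists (percentile 0.3).

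In macrophage-like cells the cytokine gene Tnf was at 0.379 (0.359 to 0.3995), Il12b, a subunit of IL-12 and IL-23, at 0.0895, and Il10 at 0.298 (0.262 to 0.338). The myeloid chemokine list was lower in 11 of 15 members (median -0.47) and the NF-kB and TLR list in 15 of 17 (median -0.32, -0.41 to -0.28). The MDSC-associated list was lower in 15 of 19 (median -0.17), the lipid-associated list in 11 of 15 (-0.28) and the classical activation list in 10 of 15 (-0.17). The alternative activation list was split, with 7 members higher and 7 lower (median -0.04), and 7 of them serve as markers of some class, of which only Mrc1 marks this one. The pro-angiogenic and cell cycle lists had medians of -0.05 and 0.00, and hypoxia and glycolysis genes were higher in 13 of 18 (median 0.16). Beside the NF-kB and chemokine lists, the dissociation stress list was lower in 15 of 17 members (median -0.33), with the heat shock gene Hspa1a at 0.254 (0.221 to 0.290). Cells were thinned to 3512 UMIs, which left out 70 AKK and 46 PBS cells. Then 60.3% of AKK against 69.1% of PBS cells had a Cd274 UMI (unthinned 81.0% against 88.9%), with 32.7% and 34.5% in T-like cells thinned alike, which are not known to lack it. For the mannose receptor gene Mrc1, a marker of this class and so not independent of its definition, the shares were 41.9% against 61.3% (unthinned 56.1% against 75.6%), with 0.954% and 3.33% in T-like cells. For Mki67 they were 8.33% against 13.2% (unthinned 20.3% against 33.5%), with 8.82% and 7.38% in T-like cells, which divide too and are no background for this gene. The interval of the difference included 0 for Arg1, Spp1, Nos2 and Trem2, the last also a marker. With each cell's class from its own marker score, the interferon-gamma median was 0.20, classical activation -0.09, lipid-associated -0.09, chemokines -0.26 and type I interferon -0.56. Scaling by the median of gene ratios moved the MDSC-associated median to -0.27, alternative activation to -0.13 and hypoxia to 0.06.

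**Figure D2:**
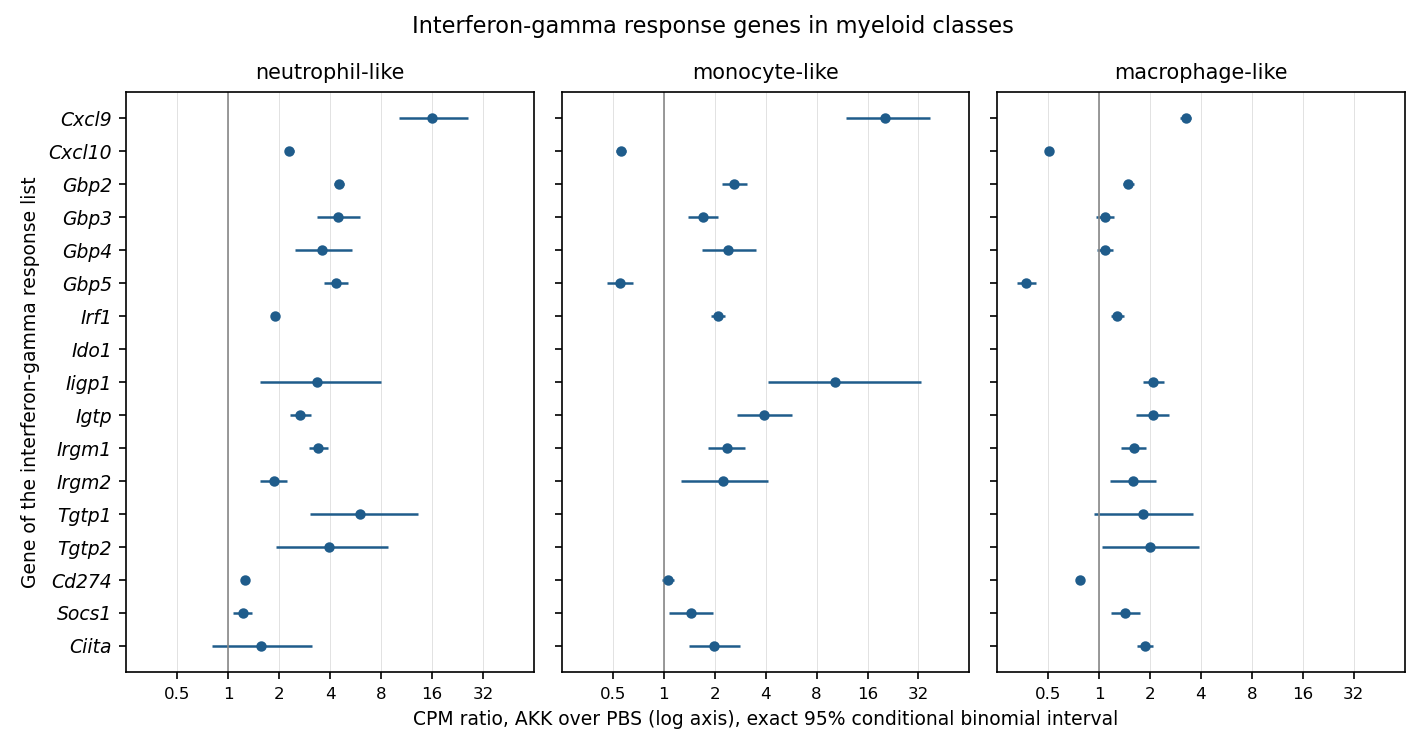
CPM ratio, AKK over PBS (log axis), for genes of the interferon-gamma response list with at least 20 UMIs, in neutrophil-like, monocyte-like and macrophage-like cells, with exact 95% conditional binomial intervals (counting error only) and a line at 1. Gbp2 lies at 4.51 in neutrophil-like and 2.62 in monocyte-like cells, and Cxcl10 at 2.29, 0.560 and 0.508.

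In T-like cells, genes of DNA replication and cell division were higher in the AKK library. All 16 measured members of the cell cycle list were higher, with a median log2 ratio of 0.72 (0.60 to 0.83). Pclaf, which binds the replication clamp (ENSMUSG00000040204, chromosome 9, 65890237 to 65903266), was at 69.8 against 5.81 CPM, a ratio of 12.0 (8.17 to 18.4). The proliferation marker gene Mki67 was at 2.09 (1.80 to 2.43). The exhaustion and checkpoint list was lower in 11 of 15 members (median -0.29, -0.32 to -0.19, percentile 0). In it, the inhibitory receptor genes Lag3 and Pdcd1, the latter encoding PD-1, were at 0.675 (0.611 to 0.747) and 0.744 (0.652 to 0.851). Cytotoxicity genes were higher in 12 of 16 (median 0.11), with the granzyme gene Gzmb at 1.41 (1.31 to 1.53). The granzyme gene Gzmf was lower, at 2.45 against 82.0 CPM, a ratio of 0.0298 (0.0185 to 0.0459). Satb1, a chromatin organiser of T cells, was at 1.498 (1.45 to 1.55) and the homing receptor gene S1pr1 at 1.46. Il7r was at 0.629 and Ccr8, a receptor gene of tumour regulatory T cells, at 0.357 (0.272 to 0.468).

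T-like cells were thinned to 3928 UMIs, which left out 86 AKK and 52 PBS cells. A Pdcd1 UMI was then seen in 15.6% of AKK (13.2 to 18.2) and 20.9% of PBS cells (17.1 to 25.2), with 25.4% against 38.0% unthinned. For other inhibitory receptor genes the shares were 19.7% against 25.5% (unthinned 27.3% against 34.99%) for Lag3, 11.8% against 16.8% (unthinned 22.95% against 28.5%) for Tigit and 48.1% against 57.4% (unthinned 62.7% against 70.2%) for Ctla4, whose CPM ratio was 0.978 (0.932 to 1.03). They were 46.0% against 36.7% (unthinned 56.1% against 43.6%) for Tcf7, a factor of naive and memory T cells. For the granzyme gene Gzmk they were 10.9% against 7.06% (unthinned 16.3% against 14.9%) and for the interferon-gamma gene Ifng 26.8% against 20.7% (unthinned 38.0% against 30.9%). Neutrophil-like cells, which should lack these transcripts, had at most 5.31% (Ctla4, AKK) in the cells deep enough to be thinned to the same number. The interval of the difference included 0 for Cd4, Cd8a, Gzmb and Foxp3, the regulatory T cell factor, and the Havcr2 shares lay at or below those of neutrophil-like cells. The regulatory T cell list was lower in 10 of 13 members (median -0.13). The naive and memory list was higher in 8 of 12 (0.12, percentile 94.5, within the range of matched random lists). The interferon-gamma response list was higher in 13 of 17 (0.18, percentile 99.65). Medians were small for MHC class I (0.10), type I interferon (-0.03), NF-kB and TLR (-0.13), hypoxia (-0.03) and dissociation stress genes (-0.09). With each cell weighted alike, the cell cycle median was 0.29, the exhaustion median -0.18 and the cytotoxicity median 0.23. The log2 ratios of Mki67, Pclaf and Gzmf were then 0.17, 1.82 and -2.28, in place of 0.99, 2.79 and -3.55. The shares of cells with a Mki67 UMI did not differ beyond counting error, at 9.29% against 7.54% (unthinned 14.4% against 16.4%), with 6.60% and 5.54% in neutrophil-like cells. The naive and memory median turned to -0.08 with clusters weighted alike, and the Ctla4 log2 ratio to 0.12 in place of -0.03. The cluster led by Lef1 and Tcf7 held 25.4% of the AKK and 18.1% of the PBS T-like cells. The shares of cells with a UMI were not weighted by cluster. With no doublets removed the NF-kB median turned to 0.06 and the interferon-gamma median was 0.36.

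In NK/ILC1-like cells, cytotoxicity genes were higher in 11 of 16 members (median log2 ratio 0.35, 0.28 to 0.48), with the perforin gene Prf1 at a ratio of 2.08 (1.89 to 2.28). The maturation and receptor list was higher in 12 of 14 (median 0.61), with S1pr5, a receptor for exit from tissue, at 4.14 (2.25 to 8.35). That list joins genes of mature NK cells, such as Itgam and S1pr5, with genes of ILC1 or less mature cells, such as Itga1 and Cd27. Its median thus gives no direction of maturation. Klra4 and Klra8 of that list also serve as markers of the class. Rap1gap2 and Rab27b, both tied to secretion of granules, had ratios of 3.17 (2.75 to 3.66) and 2.40 and the chemokine receptor gene Ccr2 2.37. The adhesion gene Cdh1 was at 0.227 (0.187 to 0.275). Cells were thinned to 4914 UMIs, which left out 54 AKK and 24 PBS cells. An Ifng UMI was then seen in 47.9% of AKK (43.2 to 52.6) and 33.6% of PBS cells (27.7 to 39.9), with 58.4% and 46.1% unthinned. Neutrophil-like cells thinned alike had 0.991% and 1.52%. The interval of the Gzmb difference included 0, and the Mki67 shares lay below those of neutrophil-like cells. Medians nearer to 0 were found for interferon-gamma response (0.13), checkpoint (0.06), MHC class I (-0.02), type I interferon (-0.15), NF-kB (-0.02), cell cycle (-0.16) and stress genes (-0.12). Hypoxia genes had a median of 0.01 and a mean of -0.05. A single cluster, with Klra8, Gzma, Eomes and Prf1 among its leading genes, held 72.0% of this class in the AKK and 51.7% in the PBS library. The shares of cells with a UMI were not weighted by cluster, so they do not separate this shift from changes within cells. With clusters weighted alike the cytotoxicity median was 0.17 and the Prf1 log2 ratio 0.63 in place of 1.04, and with no doublets removed the interferon-gamma and NF-kB medians were 0.30 and 0.37.

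B-like cells of the AKK library had higher MHC class I genes in 13 of 13 members (median log2 ratio 0.34, 0.20 to 0.43). Interferon-gamma response genes were higher in 12 of 13 (0.37) and activation genes in 11 of 13 (0.25). The low-affinity IgE receptor gene Fcer2a, a marker of mature B cells, was at 2.11 (1.72 to 2.59) and the membrane protein gene Ms4a4c at 2.31 (1.74 to 3.11). The nuclease gene Dnase1l3 was lower, at 0.382 (0.297 to 0.490). All 7 measured cell cycle genes, of 16 listed, were higher (0.39), from few UMIs (61 against 10 for Mki67). Only 3 of these 7 passed the limit against free RNA, so RNA of other cells is not excluded. The MHC class II (0.09), type I interferon (0.13), hypoxia (0.17) and stress lists (-0.08) lay nearer to 0. The NF-kB list had a median of 0.03 and a mean of -0.08.

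**Figure D3:**
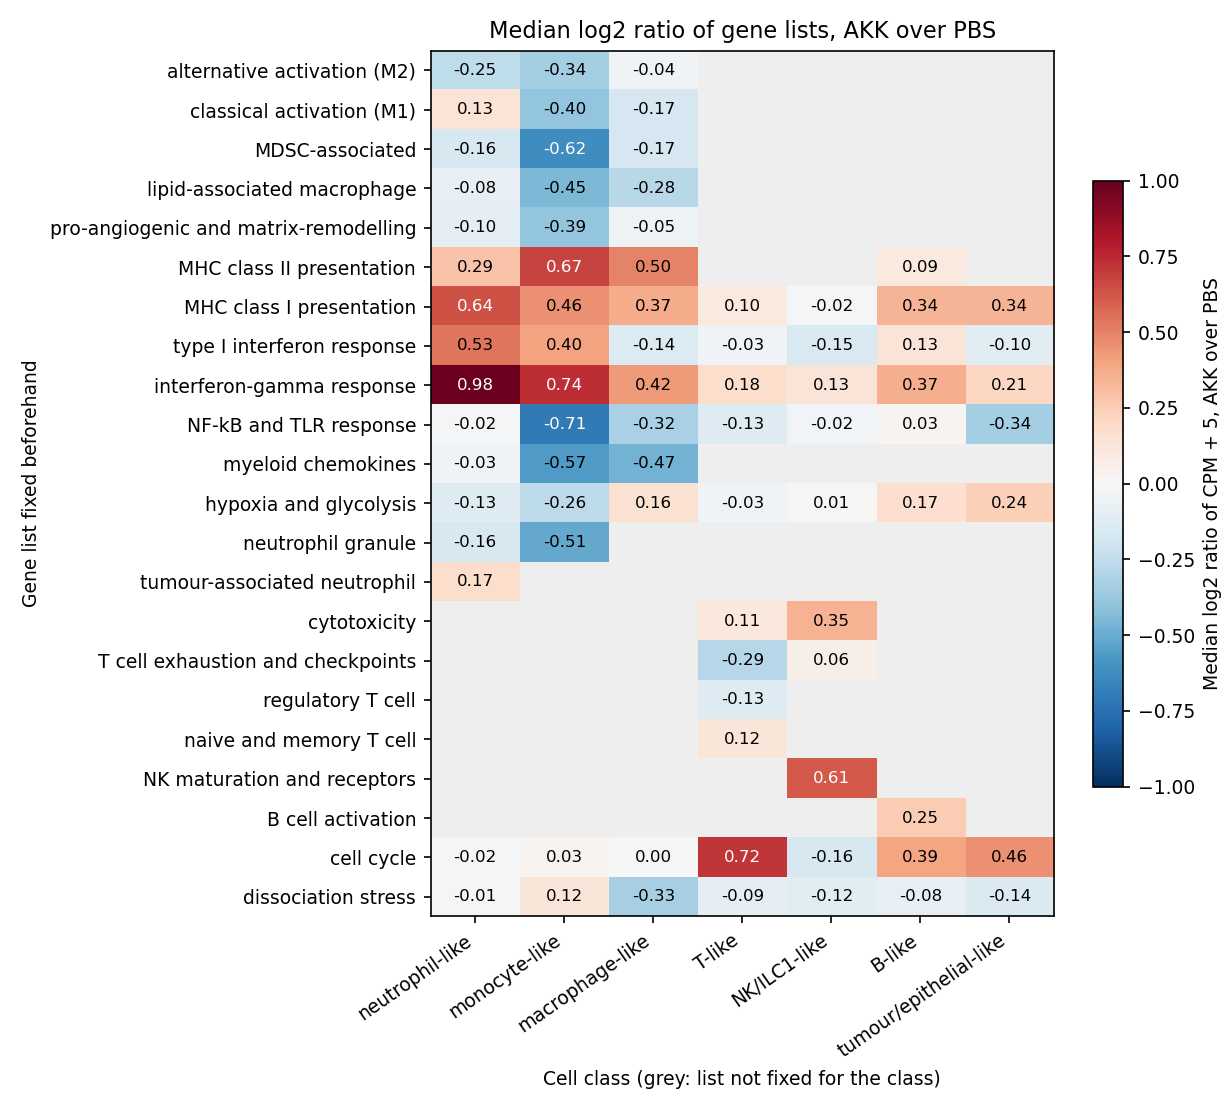
Median log2 ratio of CPM + 5, AKK over PBS, for each gene list fixed beforehand in each cell class with enough cells, in red where higher and blue where lower in the AKK library and grey where a list was not fixed for the class. The interferon-gamma response list lies at 0.98 in neutrophil-like and the NF-kB and TLR list at -0.71 in monocyte-like cells.

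Tumour/epithelial-like cells numbered 115 in the AKK and 159 in the PBS library, and whether they are impurities of the sort or doublets with leukocytes is open. They had 44.5 and 30.9 CPM of Ptprc, the CD45 gene, against 1387 and 1041 over all kept cells. Il33, an alarmin gene, was at 2.89 (2.71 to 3.09) and the mitotic gene Cenpf at 2.28 (2.11 to 2.46), and the cell cycle list was higher in 14 of 16 members (median log2 ratio 0.46). The apolipoprotein gene Apoc2 had 6 against 601 UMIs, a ratio of 0.0131 (0.00479 to 0.0287). The galectin gene Lgals2 was at 0.299 and the neutrophil chemokine gene Cxcl1 at 0.375 (0.345 to 0.407). MHC class I (0.34), hypoxia and glycolysis (0.24) and interferon-gamma response genes (0.21) were mostly higher. Of the last list, however, Cxcl9 was lower, at 0.143 (0.0960 to 0.206), as was Cxcl10, at 0.684. With no doublets removed, the log2 ratio of Cxcl10 reversed from -0.39 to 0.69 and that of Cxcl9 was -1.22 in place of -1.80. NF-kB and TLR (-0.34), stress (-0.14) and type I interferon genes (-0.10) had medians below 0. The neutrophil genes S100a8 and S100a9 were lower in this class too, at 327 against 551 and 288 against 448 CPM, and over members above the free RNA limit the NF-kB median was -0.17. With each cell weighted alike, the MHC class I median was 0.61 and the hypoxia median 0.09, and with no doublets removed the type I and interferon-gamma medians were 0.14 and 0.48. The Apoc2 log2 ratio was -2.20 in place of -3.30 with each cell's class from its own marker score.

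Over all kept cells, the 5 genes that the rule named as higher in the AKK library encode antibody chains or the chain that joins them. Ighm was at 6.86 (6.67 to 7.06), Igha, the heavy chain of IgA, at 5.30 (5.26 to 5.34), Jchain at 5.12 (5.05 to 5.19) and Igkc at 3.39 (3.38 to 3.41). Iglc1, which has near-identical copies, was at 70.0 (66.0 to 74.3), from 16 against 1 plasma-like cells with a lambda light chain. The galectin gene Lgals2 was at 0.201 (0.185 to 0.217), Ifih1 at 0.317 (0.306 to 0.327), Oasl1 at 0.352 (0.340 to 0.364) and Sash1 at 0.348. With the classes weighted to the same shares in both libraries, each of these genes had a log2 ratio nearer to 0. The log2 ratio of Igkc was 0.10 in place of 1.76, that of Igha 0.76 in place of 2.40 and that of Ifih1 -1.45 in place of -1.59. Hepatocyte transcripts were scarce, with Alb at 13 and 3 UMIs over all kept cells, and 1 member of the hepatocyte list reached the UMI minimum in the immune classes.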

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

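The settings with only barcodes over 1000 UMIs, with variable genes chosen without differing genes, with unnamed clusters in their best class, with clusters weighted alike and with members above the free RNA limit were chosen after seeing the data, as was the number of UMIs, 1500, for thinning before clustering, which left out 327 PBS and 225 AKK cells, and the choice of the list medians treated as main results; the other settings were fixed before the data were examined. No paired analysis was possible because both libraries carry the replicate number 1, which leaves a single number to share, and because the results come from no test. Of 231 values for share differences under an alternative, 224 kept their sign, of 785 list medians 750, and of 2766 log2 ratios of the 418 genes named by the rule 2702, with 444 outside the counting interval of the reported value and 19 reversed, of which the report prints Cxcl10 in tumour/epithelial-like cells, 0.69 with no doublets removed. Of 34 differences in shares of cells with a UMI, 33 kept their sign without thinning, all but Mki67 in T-like cells. B-like cells held the fewest UMIs of the classes with gene ratios, and their type I interferon, NF-kB, hypoxia and stress medians had counting intervals that included 0. Scaling by the median of gene ratios shifted log2 ratios by 0.10 in monocyte-like, 0.10 in macrophage-like and at most 0.07 in other classes. For the values that follow, the cause was not tested.

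The neutrophil-like share difference, -3.20 points as reported, was -6.42 with 4000 variable genes, -6.86 with 15 principal components, -5.53 with class from each cell's own marker score, -10.3 with each library clustered alone, -7.09 with variable genes chosen without differing genes, -7.02 with unnamed clusters in their best class and -6.18 among named immune cells. The setting with unnamed clusters in their best class counted the shallow cluster, whose type is open, as neutrophil-like. The monocyte-like difference was 0.203 with 15 components and 0.216 with each library clustered alone, where the cDC2-like value of -1.05 compares unlike classes, since no cDC1-like, mature DC-like or nonclassical monocyte-like class was named in PBS. The macrophage-like difference was -2.50 at resolution 2.0 and, with the own marker score, -6.04, where the plasma-like one was 3.12. Some settings named no nonclassical monocyte-like class (resolution 0.5, 15 components, variable genes without differing genes), no mature DC-like class (4000 variable genes, thinned, no doublet removal, without differing genes) or no cDC1-like class (thinned), and gave no value there.

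With scaling by the median of gene ratios, list medians in macrophage-like cells were -0.13 for alternative activation, -0.27 for MDSC-associated, 0.40 for MHC class II, 0.28 for MHC class I and -0.42 for NF-kB genes; in monocyte-like cells they were 0.36 for MHC class I, 0.65 for interferon-gamma response and -0.81 for NF-kB genes; in neutrophil-like cells they were -0.22 for MDSC-associated and 0.58 for MHC class I genes. With each cell weighted alike, the medians were -0.079 for classical activation, 0.35 for MHC class II and -0.23 for NF-kB genes in macrophage-like cells, -0.39, 0.49 and -0.55 for MDSC-associated, MHC class II and NF-kB genes in monocyte-like cells, 0.23, -0.18 and 0.29 for cytotoxicity, exhaustion and cell cycle genes in T-like cells, and 0.24 for cytotoxicity in NK/ILC1-like cells. With the own marker score, they were -0.091, 0.35 and 0.20 for classical activation, MHC class II and interferon-gamma response in macrophage-like cells, 0.58 for MHC class I in neutrophil-like cells, and -0.51 for both MDSC-associated and NF-kB genes in monocyte-like cells, whose shared member Il1b is the median of both. With no doublets removed, alternative activation in neutrophil-like cells was -0.14, NF-kB in monocyte-like cells -0.58 and cytotoxicity in NK/ILC1-like cells 0.23, and the NF-kB medians reversed to 0.061 in neutrophil-like and 0.060 in T-like cells. With clusters weighted alike, MHC class I in neutrophil-like cells was 0.59 and cytotoxicity in NK/ILC1-like cells 0.17, and the neutrophil granule and the naive and memory T cell medians reversed to 0.073 and -0.080. With a pseudocount of 1 CPM, alternative activation and interferon-gamma response in neutrophil-like cells were -0.32 and 1.38, interferon-gamma response in macrophage-like cells 0.59, MHC class II in monocyte-like cells 0.78 and cell cycle in T-like cells 0.91. Over members above the free RNA limit, MDSC-associated genes were -0.069 in neutrophil-like and -0.14 in macrophage-like cells, interferon-gamma response in neutrophil-like cells 1.203, and the NF-kB median in T-like cells reversed to 0.0026. With at least 500 genes per cell, MHC class II in monocyte-like cells was 0.45.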

Other observations

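The tests of T-like against neutrophil-like cells, of T clusters, of plasma-like and gamma-delta T-like against B-like cells, of the stress list in monocyte-like cells and of Ifng per kept cell were chosen after the results were seen. The other tests were written before their own results were seen, but those on barcodes with at least 1000 UMIs and on clusters weighted alike use settings chosen after seeing the data.

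Among plasma-like cells, IgA was the main heavy chain in 154 of 223 AKK cells (69.1%, 62.5 to 75.1) and 31 of 52 PBS cells (59.6%, 45.1 to 73.0), so that per 1000 kept cells there were 24.95 and 6.68 IgA cells. IgG was the main chain in 56 and 21 cells and IgM in 13 of 223 AKK cells and 0 of 52 PBS cells, with an upper binomial limit of 6.85%. Il17a, a cytokine gene of gamma-delta T cells and a marker of that class, was at 16.03 against 3.30 CPM over all kept cells, a ratio of 4.85 (4.17 to 5.67), beside 101 against 27 gamma-delta T-like cells. With the classes weighted to the same shares, its log2 ratio of CPM + 5 was 0.44 in place of 1.34. Tumour/epithelial-like cells had 3.66 and 4.56 CPM of the Y-linked Ddx3y in the AKK and PBS libraries against 141 and 132 over all kept cells.

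Lymphocytes held a larger and macrophage-like cells a smaller share in the AKK library. An excess of shallow barcodes called as cells in the PBS library is argued against, because among barcodes with at least 1000 UMIs, clustered anew, the lymphocyte difference kept 97.0% of its size and the macrophage difference 104%. A loss of macrophages alone would raise all other classes by 1 factor, whereas the odds of a T-like against a neutrophil-like cell differed by a ratio of 1.60 (1.41 to 1.82). More circulating blood cells in the AKK sample stay open, since T-like cells of the cluster led by Lef1 and Tcf7, genes of naive cells, gained on those of the Cd8a cluster (odds ratio 1.53, 1.12 to 2.11), although plasma-like and gamma-delta T-like cells, scarce in blood, gained on B-like cells (odds ratio 2.34, 1.70 to 3.25), which blood alone would not give. An effect of the bacterium on recruitment may also account for it and is untested here, as animals and libraries cannot be separated with 1 library per group.

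The interferon-gamma response list was higher in neutrophil-like, monocyte-like and macrophage-like cells of the AKK library. Free RNA would raise these genes in T-like cells too, if less in CPM, since these cells held more UMIs. Their medians were 8888 in the AKK and 9452 in the PBS library, against 4162.5 and 4939 in neutrophil-like cells. The median gain in CPM of the 17 members in T-like cells was only 0.0720 of the gain in neutrophil-like cells. Monocyte-like and macrophage-like cells were not compared in this way. With clusters of a class weighted alike, the median kept 93.0% of its size in the class where it kept less, of neutrophil-like and monocyte-like cells, and 102% in the other. In neutrophil-like cells this argues against shifted proportions of these clusters. In monocyte-like cells the larger cluster held 90.2% of the AKK and 91.5% of the PBS cells, so the weighting could change little. Macrophage-like cells formed a single cluster, so it could not be applied there. Shifts in make-up within a cluster stay open. A candidate explanation, as a hypothesis, is more interferon-gamma from T-like and NK/ILC1-like cells: Ifng UMIs per 1000 kept cells were 375 against 215, a ratio of 1.74 (1.62 to 1.88), with CPM ratios of 1.28 within T-like and 1.31 within NK/ILC1-like cells. It was found and tested on the same libraries, and a difference between the animals that is unrelated to feeding stays open.

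NF-kB and TLR genes were lower in monocyte-like and macrophage-like cells of the AKK library. More stress from dissociation in the PBS sample would leave the stress list lower in the AKK library. In monocyte-like cells the list was not lower (median log2 ratio 0.12, 0.08 to 0.18, 12 of 17 members). Nor did it stand above other genes (percentile 75.4 among matched random lists). In monocyte-like cells matched on their share of stress gene UMIs, the stress median was 0.003 and the NF-kB median kept 112% of its size. These values argue against stress as the cause there. Stress stays open in macrophage-like cells, where the stress list was lower (median -0.33). There the NF-kB median kept 97.7% of its size in cells matched on their share of stress gene UMIs, but the matching left the stress median at -0.23, so stress cannot be told apart from other differences. In monocyte-like cells, neutrophil RNA or doublets with neutrophils in the PBS library could account for 28.0% of the CPM lost over the list, too little for the whole and too much to set aside, so this explanation cannot be told apart from a difference in the monocytes. Whether feeding lowers these genes was not tested beyond this pair of libraries.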
